A study of Homo sapiens with 4 samples.

How the data were processed

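RNA was measured by sequencing in MDA-MB-231, an established human cell line of triple-negative breast cancer (tumours that lack the oestrogen and progesterone receptors and HER2). There were 4 libraries: 2 of wild-type cells (WT) and 2 of cells whose genotype the labels give as a knockout of the microRNA miR-3662 (KO). Per the labels' protocols, total RNA was taken up in Trizol and made into libraries with an Illumina TruSeq RNA kit. The series title speaks of CRISPR interference and activation, which change transcription without deleting a gene, and its design text of cells sorted by the activity of the microRNA. The sample labels give a knockout genotype, and the groups here follow the sample labels, so what KO stands for remains uncertain. The labels do not say how the knockout was made, nor whether the libraries came from separate cultures or clones. The p-values given here therefore measure only the spread between these samples, which may be technical.

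The authors deposited a table with 1 FPKM value (fragments scaled by transcript length in kilobases and by the mapped fragments of the library) per gene and library, per the file headers. The values carry 2 decimals. The tools named in the submitters' processing notes are HISAT, StringTie, Cufflinks and GATK, with the genome build hg38 and no roles or versions. Which of them made the FPKM values, and with which filter, is not given in the sources used here. The table listed 20804 genes, of which 1029 were gene models without a RefSeq gene. A spreadsheet had turned 11 symbols into dates, and these were restored from the gene identifiers. Of the identifiers, 19694 were found in the RefSeq gene table (GRCh38.p14), and 18644 genes were placed on GRCh38 with the GENCODE 29 annotation. No gene of the mitochondrial genome was listed, so the mitochondrial list gave no value. All columns of per-sample values matched 1 sample each.

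Depth is not stated and read counts were not used here. FPKM divides by depth, so the precision of a gene with few reads cannot be read from its value. The steps between low values of genes listed at 0 in some library were tried as a measure of relative depth. Against the first WT library the best ratio was matched within 3% by only 9 of 69 genes compared in the second WT library, 7 of 48 in the first KO library and 9 of 52 in the second. Whether chance would match as many was not tested, so no relative depth is given. Whole reads were not recovered, because gene lengths as used by the authors are not given in the sources used here.

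FPKM values were analysed as log2(FPKM + 1), so a log2 fold change understates the change of genes with low values. Genes with at least 1 FPKM in at least 2 libraries were tested, without further scaling, with limma 3.58.1 (R 4.3.3), using the moderated test with a mean-variance trend and Benjamini-Hochberg adjustment over all tested genes, at an adjusted p under 0.05. All p-values of single genes come from this fit. Gene lists fixed before the data were examined (40 lists, 37 with at least 2 tested members) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. Camera compares a list with all other tested genes, whereas fry asks whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction. Members were also counted after an adjustment over the list alone. Some lists, such as the antigen presentation, ribosomal protein and histone lists, hold genes that share reads with near-identical copies, and how the authors split such reads is not given in the sources used here. Tables were handled in Python 3.11.15 with pandas 2.3.3.

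Genes were named by a rule fixed before the data were examined. It took HBP1, HIF1A, CTNNB1, AXIN2, CCND1, MYC, HBS1L and MYB. It then took the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 2 FPKM, a gene symbol and KO values all above or all below the WT values. For each list that passed its test or had at least 3 changed members, it took the 2 rising and the 2 falling members with the smallest p. Genes outside this rule are said to have been picked after their values were seen. Some genes that the rule takes are not reported here.

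Sites for the microRNA were sought in the longest annotated 3′ UTR of each gene (GENCODE 29) as matches of 7 nucleotides to positions 2 to 8 of the mature microRNA, whose precursor was located in GRCh38. The difference in median log2 fold change between genes with and without a site, within bins of 3′ UTR length, was ranked among the 42 7-mers of the same base composition. Genes are not independent replicates, so the rank describes these libraries.

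The fit was tested on simulated data for KO against WT with 11786 genes. It found 1.5% of 68 genes changed by a log2 value of 0.5, 78.8% of 66 genes changed by 1, and 100% of 66 genes changed by 2. Of its 127 calls, 8 were false. Only these few planted genes changed in the simulation, whereas 27% of tested genes were called in the data. What the adjustment finds depends on that share, so the simulated percentages need not hold for the data. The site test, run on 10833 genes with a planted rise of 0.15, ranked the planted 7-mer in place 1. Its simulated fold changes held no trend with 3′ UTR length or base content. The planted rise was also larger than the difference of 0.029 found in the data. Whether the test would find so small a difference is therefore not known.

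Alternatives fixed before the data were examined were scaling by the median of ratios between libraries, no filter and a stricter filter on low values, a replicate block, limma without the trend or with array weights, a pseudocount of 0.1, a fold threshold, and leaving out each library in turn. A correction for GC content, a crossed block, leaving out gene models without a RefSeq gene and leaving out the end of chromosome 6q were added after seeing the data.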

Results

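Gene expression was measured by RNA sequencing in 4 libraries of MDA-MB-231 cells, 2 WT and 2 with a knockout of miR-3662. The FPKM values summed to 504102 and 520527 in the WT libraries and to 528986 and 544650 in the KO libraries. At least 1 FPKM was reached by 11283 and 11344 genes in WT and by 11720 and 11723 genes in KO, and 3324, 3308, 3022 and 2994 genes were listed at 0. Ranked over all genes, the libraries correlated at 0.979 within WT (Spearman, across genes), at 0.980 within KO and at 0.966 to 0.970 between the groups. The microRNA itself is too short for such libraries and was not among the measured genes, so the table does not check the knockout. In GRCh38 its precursor of 95 nucleotides lies on chromosome 6 from 134979338 to 134979432, on the minus strand, in an intron of HBS1L.

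The first comparison asked which genes differed between KO and WT cells. CSF1, a growth factor of macrophages, rose from 19.8 ± 6.87 to 169 ± 54.9 FPKM (mean ± SD, n = 2 per group), a log2 fold change of 3.03 ± 0.27 (SE). BMP4, a secreted factor of the TGF-β family, rose by 2.92, the paraspeckle RNA NEAT1 by 2.73, the calcium-binding protein gene S100A4 by 2.65, the lysosomal protease gene CTSD by 2.47 and the matricellular protein gene WISP2 by 2.39. In the other direction, the long non-coding RNA UCA1 fell by 4.15 on the log2 scale, from 17.4 ± 0.375 to 0.035 ± 0.0212 FPKM, and GRAMD1B, which encodes a sterol transfer protein, fell by 3.92. The cytokine gene IL11 fell by 3.18, from 125 ± 6.30 to 13.0 ± 1.68 FPKM, and KISS1, the precursor gene of the kisspeptins, fell by 2.29.

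Of 11786 tested genes, 3184 (27%) changed at an adjusted p under 0.05, with 1906 higher and 1278 lower in KO. The number with a log2 fold change of at least 1 in size was 546, with 415 higher and 131 lower. After scaling the libraries by the median of ratios, 3241 genes changed, with 1413 higher and 1828 lower, so the balance of rises and falls depended on the scaling. The 2 scalings shared 2691 calls and none had opposite directions. The 2 KO values lay both above or both below the 2 WT values in 68% of tested genes, against 33.3% by chance. Without the first or the second WT library 1402 and 1741 genes changed, and without the first or the second KO library 1902 and 1453.

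Among the 12 largest rises were also RFPL4A (2.98), AKR1C3 (2.87), CST4 (2.83), RFPL4AL1 (2.72), SAA1 (2.57) and ATP23 (2.56). RFPL4A and RFPL4AL1, AKR1C3, CST4 and SAA1 have close copies in the genome that share reads, so their values are uncertain. ATP23 stood at 0.115 ± 0.0354 FPKM in WT and at 5.61 ± 0.912 in KO. The adjusted p of the 12 rises ranged from 0.000106 for NEAT1 to 0.00312 for BMP4. Among the 12 largest falls were PAEP (-3.29), C16orf45 (-2.60), the TGF-β co-receptor gene ENG (-2.20), the metalloprotease gene ADAMTS6 (-2.20), the transcription factor gene GATA2 (-2.12), the actin-binding protein gene TAGLN (-2.07), MPP4 (-2.06) and FLNC (-2.03), which encodes a filamin. Their adjusted p ranged from 4.60e-05 for UCA1 to 0.0114 for TAGLN. UCA1, GRAMD1B and PAEP were at 5 FPKM or more in both WT libraries and at 0.5 or less in both KO libraries, as was 1 gene model without a RefSeq gene, and no gene showed the opposite. Without the first WT library the fall of TAGLN no longer passed (adjusted p 0.0567).

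**Figure D1:**
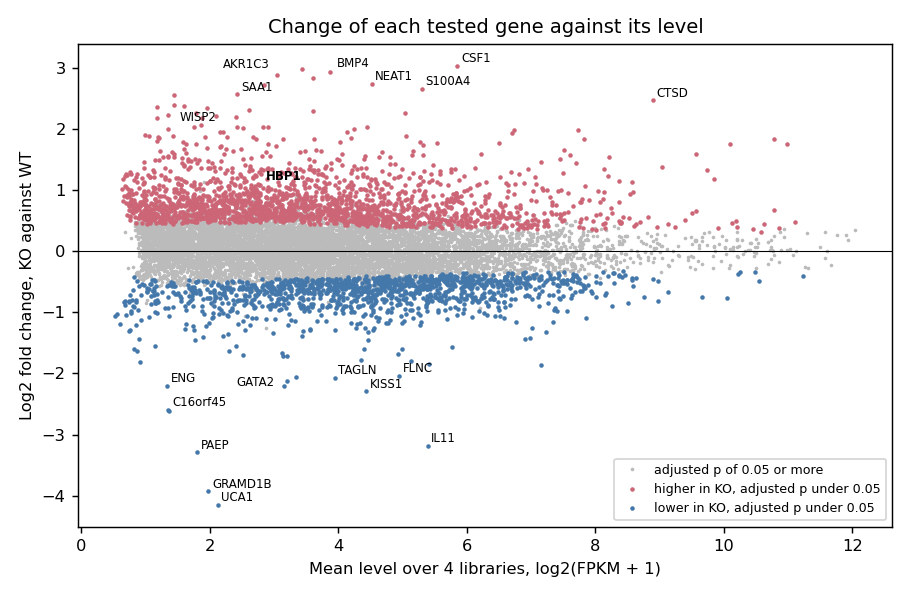
Log2 fold change of KO against WT (y axis, scale of log2(FPKM + 1)) against the mean log2(FPKM + 1) of the 4 libraries (x axis) for the 11786 tested genes, with genes past an adjusted p of 0.05 in colour. UCA1 (-4.15) and CSF1 (3.03) lie at the lower and upper ends.

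The second comparison concerned HBP1, the transcriptional repressor that the series title joins with miR-3662. HBP1 (gene identifier 26959, chromosome 7 from 107168961 to 107202529, plus strand, GRCh38) was at 2.97 and 4.66 FPKM in the WT libraries and at 8.35 and 9.71 in the KO libraries. It rose from 3.82 ± 1.20 to 9.03 ± 0.962 FPKM (mean ± SD, n = 2), a log2 fold change of 1.08 ± 0.20 (SE) with an adjusted p of 0.0090 in limma. Without the second KO library the log2 fold change was 0.98 with an adjusted p of 0.0616, and without the filter on low values the adjusted p was 0.0772. HIF1A, the oxygen-regulated transcription factor gene, rose from 45.4 ± 8.29 to 70.0 ± 8.47 FPKM (log2 fold change 0.62, adjusted p 0.0254). MYC fell from 102 ± 0.0495 to 68.5 ± 3.34 FPKM (-0.57, adjusted p 0.0102). CTNNB1, the gene of β-catenin, was at 104 ± 0.0424 and 112 ± 2.12 FPKM (0.10, adjusted p 0.490), and CCND1 at 108 ± 11.9 and 105 ± 15.5 FPKM (-0.043, adjusted p 0.840), so neither passed. AXIN2 was at 0.805 ± 0.00707 and 0.290 ± 0.0990 FPKM and MYB at 0.285 ± 0.00707 and 0.15 ± 0.0424 FPKM, both below the filter. HIF1A did not pass without the second WT library (adjusted p 0.145), without the first KO library (0.106), without the filter on low values (0.116) or after a GC correction added after seeing the data (0.36, adjusted p 0.0836). MYC did not pass without the first or the second WT library (0.0635 and 0.0584) or without the filter (0.0509).

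**Figure D2:**
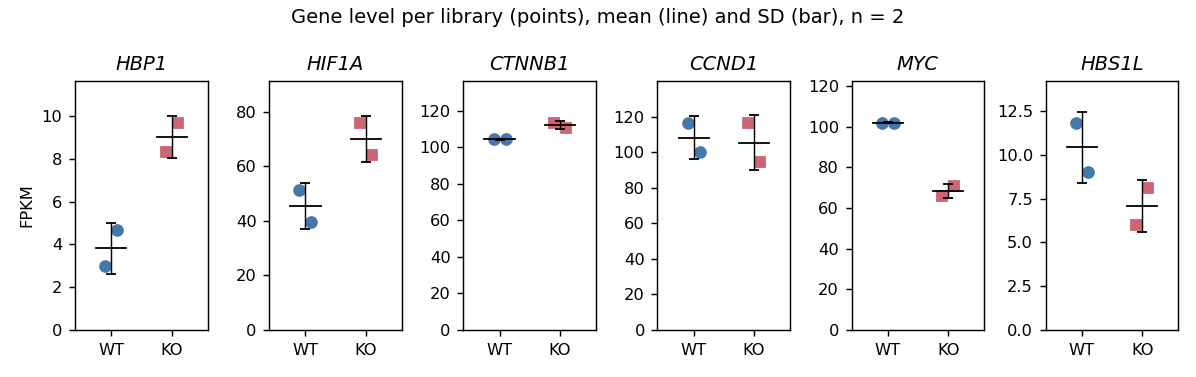
FPKM of HBP1, HIF1A, CTNNB1, CCND1, MYC and HBS1L in each library (points), with the group mean (line) and SD (bar), n = 2 per group. Both KO values of HBP1 (8.35 and 9.71) lie above both WT values (2.97 and 4.66).

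The third comparison asked whether fixed gene lists shifted. Of 37 lists tested with camera, 8 passed, with 5 higher and 3 lower in KO, and 7 passed after scaling. None passed camera with an estimated correlation (adjusted p 0.922 for each of the 8 lists, and 0 of 37 lists with an unadjusted p under 0.05) and none passed fry (lowest adjusted p 0.0559, 8 lists with an unadjusted p under 0.05), while 31 passed the mixed form of fry. With an estimated correlation camera rests on the 2 residual degrees of freedom that 4 libraries leave, so it has little power here. The Wnt feedback and target list had an estimated correlation of 0.0144, near the preset 0.01. Its unadjusted camera p still went from 0.0032 to 0.103. These failures alone therefore cannot tell whether correlation between genes undoes a call. Other passing lists had estimates far above the preset, 0.692 for antigen presentation, 0.527 for cholesterol synthesis, 0.373 for ATF4 and 0.277 for interferon response. For NF-κB and hypoxia the estimates were 0.0838 and 0.0499, and for endothelial markers -0.853. Where the estimate is high, the p at the preset correlation may be too small, so those calls are less certain. Members that changed are counted over all genes tested, then adjusted over the list alone, and then over all genes after scaling by the median of ratios. Members named without a fold change were picked after their values were seen.

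Genes of antigen presentation by MHC molecules were higher in KO. Of 15 tested members 14 rose and 1 fell (14 and 1 adjusted over the list alone, 13 and 1 after scaling), with a median log2 fold change of 1.32 (camera adjusted p 9.86e-06, and unadjusted p = 0.235 with an estimated correlation). B2M, the light chain of class I molecules, rose from 327 ± 34.3 to 847 ± 91.4 FPKM (1.37), and the immunoproteasome gene PSMB10 rose from 7.79 ± 0.361 to 29.5 ± 5.76 FPKM (1.79). TAP2, a subunit of the peptide transporter, fell by 0.67. HLA-B, HLA-C and HLA-E also rose, but share reads with one another. Of the interferon response list, 16 of 29 tested members rose and 1 fell (16 and 3 adjusted over the list alone, 12 and 3 after scaling), with a median of 0.68 (camera adjusted p 0.0038, and unadjusted p = 0.301 with an estimated correlation). GBP2 rose by 1.78 and IFITM3 by 0.97, as did the regulators STAT2, IRF1, IRF7 and IRF9. IFI44 fell by 1.09, and ISG15 was at 108 ± 55.1 FPKM in WT and 52.4 ± 0.0778 in KO (-0.94, adjusted p 0.0506). Without the first WT library the interferon list did not pass (camera adjusted p 0.0983).

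NF-κB targets and inflammatory genes were higher in KO, with 12 of 22 tested members up and 1 down (13 and 1 adjusted over the list alone, 12 and 1 after scaling) and a median of 0.57 (camera adjusted p 0.0038, and unadjusted p = 0.151 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose by 2.20 and CSF1 by 3.03, and IL6, LIF, NFKBIA, NFKB2 and RELB rose as well. IL11 fell by 3.18. Without the filter on low values the list median was 0.20 and the list did not pass (adjusted p 0.298). Of the apoptosis list, 4 of 23 members rose and none fell (4 and 0 adjusted over the list alone), among them BIRC3 and BMF (1.16), against 3 rises and 4 falls after scaling. BAK1 (-0.32) and MCL1 (-0.27) did not pass. The list did not pass (camera adjusted p 0.818).

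Hypoxia-responsive genes were higher in KO. Of 28 tested members 17 rose and 2 fell (20 and 2 adjusted over the list alone, 16 and 2 after scaling), with a median of 0.74 (camera adjusted p 0.0038, and unadjusted p = 0.123 with an estimated correlation). The mitophagy receptor gene BNIP3L rose from 16.0 ± 1.06 to 44.6 ± 4.40 FPKM (1.42) and PFKFB4, an enzyme that controls glycolytic flux, rose by 1.29. ADM, the gene of adrenomedullin, fell by 1.69 and JMJD6 by 1.06. VEGFA was at 24.5 ± 4.03 and 24.1 ± 5.45 FPKM. Of 21 glycolysis genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, 6 and 1 after scaling). ALDOC rose by 1.84 and ENO2 by 1.17, HK2 fell by 0.82, and HK1 (-0.24) did not pass. Of 45 nuclear genes of oxidative phosphorylation 11 rose and 1 fell (15 and 1 adjusted over the list alone, 9 and 1 after scaling), with COX7C (0.63) and NDUFA4 (0.63) higher, SDHA (-0.57) lower and NDUFA8 (-0.23) not passing. Neither of these 2 lists passed (camera adjusted p 0.193 and 0.0540).

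Cholesterol synthesis genes were higher in KO, with 11 of 25 tested members up and 1 down (11 and 1 adjusted over the list alone, and 6 and 1 over all genes after scaling) and a median of 0.51 (camera adjusted p 0.0038, and unadjusted p = 0.406 with an estimated correlation). The sterol reductase gene TM7SF2 rose by 1.71, and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 1.62. ACAT2 fell by 0.68, and MVD (-0.058) did not pass. The list did not pass without the second WT library (adjusted p 0.0540) or the second KO library (0.0571). Of 17 fatty acid synthesis genes 5 rose and none fell (5 and 0 adjusted over the list alone), among them SCD (1.21) and ACSS2 (0.89), while FASN (-0.33, adjusted p 0.101) and ACLY (-0.22) did not pass and the list did not pass (0.526). After scaling 4 of these genes rose and FASN fell (adjusted p 0.0434).

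Genes of the ATF4 amino acid response were lower in KO. Of 23 tested members 9 fell and 1 rose (10 and 1 adjusted over the list alone, 11 and 1 after scaling), with a median of -0.39 (camera adjusted p 0.0038, and unadjusted p = 0.331 with an estimated correlation). The amino acid transporter gene SLC7A5 fell from 228 ± 15.1 to 132 ± 1.73 FPKM (-0.78), the one-carbon enzyme gene MTHFD2 fell by 1.05, and ATF4 itself fell. DDIT4, an inhibitor of mTORC1 that hypoxia also induces, rose by 1.46, and SLC7A11 (0.37) did not pass. Without the second WT library the list did not pass (adjusted p 0.0540). Of 24 genes of the unfolded protein response of the endoplasmic reticulum 3 rose and 2 fell (3 and 2 adjusted over the list alone, 3 and 3 after scaling), with DNAJB9 (1.04) and CANX (0.60) higher and HSPA5 (-0.61) and HYOU1 (-0.48) lower. In the heat shock list 2 of 16 fell and none rose (2 and 0 adjusted over the list alone, 5 and 0 after scaling), HSP90AB1 by 0.77 and CHORDC1 by 0.79. Neither of these 2 lists passed (camera adjusted p 0.908 and 0.175).

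Wnt feedback genes and targets were lower in KO, with 4 of 16 tested members down and none up (5 and 0 adjusted over the list alone, 6 and 0 after scaling) and a median of -0.23 (camera adjusted p 0.0171, and unadjusted p = 0.103 with an estimated correlation). ID2, a repressor of differentiation, fell by 1.02, JUN fell from 76.2 ± 3.06 to 39.97 ± 3.02 FPKM (-0.92), and DKK1, a secreted Wnt antagonist, and MYC also fell. SNAI2 (0.41) and BAMBI (0.16) did not pass. Several of these members have other known inputs, as JUN is an immediate early gene. The list did not pass without the second KO library (adjusted p 0.0571), over genes with at least 5 FPKM (0.121) or after the GC correction added after seeing the data (0.0606). Of 26 components of the Wnt pathway 3 rose and 3 fell (1 and 3 adjusted over the list alone), against 1 and 6 after scaling. PORCN, the acyltransferase of Wnt ligands, rose by 1.03 and DKK3 by 0.45, and WNT10B fell by 0.72 and AXIN1 by 0.52. Of 9 tested genes reported as HBP1 targets, MIF rose by 0.49 and DNMT1 (-0.72) and MYC (-0.57) fell (1 and 2 adjusted over the list alone, 1 and 2 after scaling), while CDKN1A (0.22) did not pass. Neither of these 2 lists passed (camera adjusted p 0.526 for each).

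Cell cycle genes moved little as lists. Of 42 S phase genes 7 fell and 1 rose (6 and 1 adjusted over the list alone, 10 and 1 after scaling), with RRM2, a subunit of ribonucleotide reductase, falling by 0.75 and the maintenance methylation cofactor gene UHRF1 by 0.76, while CENPU rose by 0.81 and CASP8AP2 (0.47) did not pass. Of 54 G2 and M phase genes 4 rose and 7 fell (3 and 7 adjusted over the list alone, 2 and 7 after scaling). HMMR (0.79) and the kinase gene CDK1 (0.66) rose, and CDC20 (-0.74) and HN1 (-0.66) fell. Of 13 CDK inhibitor and senescence genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, 2 and 1 after scaling), with IGFBP7 (1.58) and GDF15 (1.25) higher, and IGFBP3 (-0.44) not passing. Of 23 p53 targets 6 rose and 2 fell (6 and 2 adjusted over the list alone, 4 and 2 after scaling), with TP53I3 (1.27) and GDF15 higher and AEN (-1.03) and SESN2 (-0.49) lower. The camera adjusted p of these 4 lists were 0.167, 0.557, 0.398 and 0.573.

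Genes of the mesenchymal and epithelial states changed in both directions. Of 26 mesenchymal genes 6 rose and 6 fell (7 and 7 adjusted over the list alone, 4 and 7 after scaling). S100A4 rose by 2.65 and the matrix cross-linking enzyme gene LOX by 0.90, and the matricellular protein gene CTGF fell from 270 ± 10.1 to 73.5 ± 3.06 FPKM (-1.86) and TGFBI by 1.44. Of 16 epithelial genes 4 rose and 4 fell (4 and 4 adjusted over the list alone, 3 and 4 after scaling), with ELF3 (1.26) and SPINT2 (1.03) higher and the keratin genes KRT8 (-1.10) and KRT18 (-0.61) lower. Of 19 matrix protease and invasion genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, 6 and 2 after scaling), with CTSD and S100A4 higher and ADAMTS1 (-0.60) not passing. Of 25 integrin and adhesion genes 8 rose and 4 fell (9 and 6 adjusted over the list alone), against 6 and 6 after scaling. ITGAV (1.26) rose, and the focal adhesion genes ZYX (-1.05) and PXN (-0.89) fell. Of 22 YAP and TEAD targets 2 rose and 4 fell (2 and 4 adjusted over the list alone, 1 and 5 after scaling), with MYOF (0.88) and TGFB2 (0.89) higher and CTGF and F3 (-0.76) lower. The camera adjusted p of these 5 lists were 0.472, 0.818, 0.255, 0.658 and 0.272. Of 11 genes of stem-like breast cancer cells NOTCH1 fell by 0.93 (0 rose and 1 fell adjusted over the list alone, 0 and 2 after scaling), and the list did not pass (0.763).

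**Figure D3:**
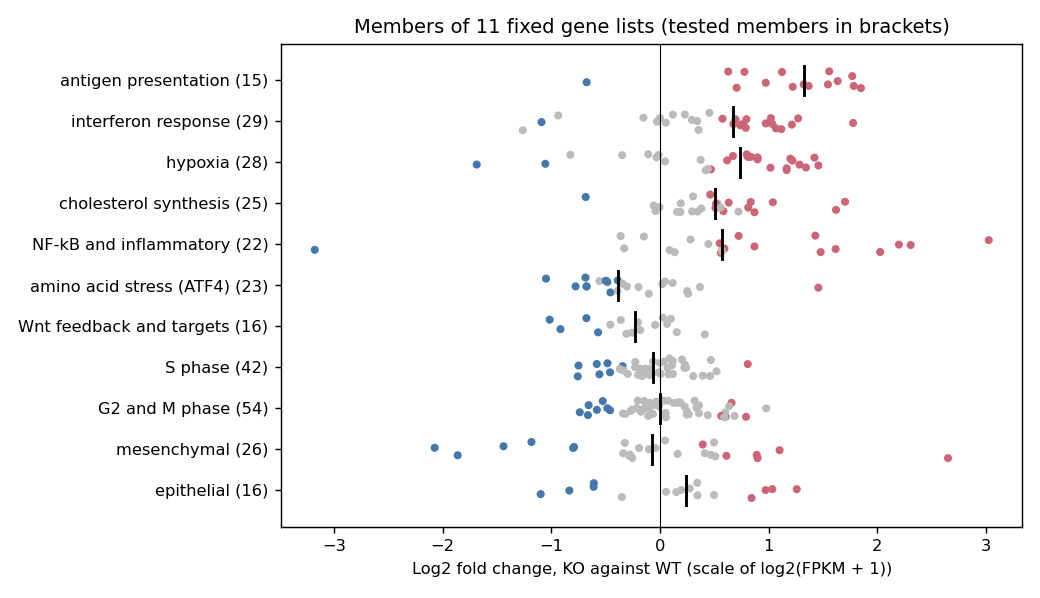
Log2 fold change (x axis) of each tested member of 11 fixed gene lists (points, with the number of tested members in brackets), with genes past an adjusted p of 0.05 in red (higher in KO) or blue (lower) and the list median as a line. The medians run from 1.32 for antigen presentation to -0.39 for the ATF4 list.

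Of 26 immediate early genes 3 rose and 4 fell (3 and 4 adjusted over the list alone, 2 and 6 after scaling), with KLF6 (0.92) and DUSP6 (0.76) higher and JUN and IER2 (-0.82) lower. Of 25 genes of EGFR, RAS and PI3K signalling 4 rose and 1 fell (0 and 1 adjusted over the list alone), with EREG (0.63) and FGFR1 (0.58) higher, HBEGF (-0.79) lower and EGFR (-0.40) not passing, against 1 and 2 after scaling. Of 13 microRNA pathway genes PRKRA (0.71) and AGO4 (0.54) rose and XPO5 (-0.74) and AGO2 (-0.64) fell (2 and 2 adjusted over the list alone, 1 and 3 after scaling). Of 74 cytosolic ribosomal protein genes 7 rose and 4 fell (4 and 2 adjusted over the list alone), with RPS27 (0.67) and RPS29 (0.48) higher and RPL7A (-0.48) and RPL35 (-0.41) lower, and after scaling 4 rose and 11 fell, so the balance flips. Of 7 replication-dependent histone genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 2 after scaling), HIST1H1C by 1.21 upward and HIST1H2AC (-1.28) and HIST1H2BK (-0.84) downward, while HIST1H4H (0.30) did not pass. None of these 5 lists passed (camera adjusted p 0.526, 0.710, 0.526, 0.622 and 0.557). The median, the mean and the direction of the test differed in sign for 7 lists, namely Wnt components, G2 and M phase, stem-like cells, immediate early genes, apoptosis, EGFR, RAS and PI3K signalling, and fibroblast markers.

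Markers of other cell types were mostly near 0. The leukocyte genes PTPRC and CD3E were listed at 0 in all 4 libraries, and of 10 listed leukocyte markers 8 stayed below 1 FPKM. CD68, a lysosomal protein gene, rose from 34.6 ± 6.28 to 92.4 ± 34.9 FPKM (1.35) and ITGB2 by 0.93 (2 and 0 adjusted over the list alone, 2 and 0 after scaling, camera adjusted p 0.167). Of 9 endothelial markers 7 stayed below 1 FPKM, and the tested ones, ESAM (-0.99) and TIE1 (-0.81), fell (0 up and 2 down adjusted over the list alone, 0 and 2 after scaling). That list passed (camera adjusted p 0.0337, and unadjusted p = 0.114 with an estimated correlation) but not after scaling (0.0625), without the filter (0.433), or, in settings added after seeing the data, after the GC correction (0.0826) or with the crossed block (0.0607). All 4 listed erythroid markers stayed below 1 FPKM and none was tested. Of the fibroblast markers FBLN1 (0.94) rose and COL1A1 (-0.79) fell (1 and 1 adjusted over the list alone, 1 and 1 after scaling, camera adjusted p 0.908), and 6 of 8 stayed below 1 FPKM. PAX8, from a list of kidney and neural markers of HEK293 cells, rose from 0.655 ± 0.0212 to 1.98 ± 0.0212 FPKM (0.85), and SIX2 (-0.30) did not pass (1 and 0 adjusted over the list alone, 1 and 0 after scaling, camera adjusted p 0.719). Of 7 luminal breast markers MLPH (0.91) and CA12 (0.47) rose and KRT8 and KRT18 fell (2 and 2 adjusted over the list alone, 1 and 2 after scaling, camera adjusted p 0.992). Of 4 basal breast markers 1 rose and 1 fell, FOXC1 by 0.88, and EGFR did not pass (1 and 2 adjusted over the list alone, 1 and 2 after scaling, camera adjusted p 0.526).

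Genes near the microRNA were examined as a fixed list of neighbours. HBS1L, whose intron holds the precursor (chromosome 6 from 134960378 to 135103056, minus strand, GRCh38), was at 10.4 ± 2.01 FPKM in WT and 7.07 ± 1.499 in KO (-0.50 ± 0.19, adjusted p 0.0894). It passed after scaling (-0.60, adjusted p 0.0492) and, in settings added after seeing the data, after a GC correction (-0.72, adjusted p 0.00452) and with a crossed block (adjusted p 0.0209). Without the first WT or the first KO library it was -0.32 or -0.31 and did not pass (adjusted p 0.348 for each). MTFR2 fell from 14.8 ± 0.0636 to 9.67 ± 0.120 FPKM (-0.57, adjusted p 0.0195), while AHI1 (0.054) and PDE7B (0.16) did not pass. Of 6 tested neighbours 1 fell and none rose (1 and 0 adjusted over the list alone, 2 and 0 after scaling), and the list did not pass (camera adjusted p 0.193). The long arm of chromosome 6 was then examined because of its values. Of the 94 tested genes that begin beyond the precursor, up to 170584692, 60 fell and 1 rose, with a median log2 fold change of -0.62. Relative to all tested genes the median was -0.69 (95% bootstrap interval -0.76 to -0.64), and it was -0.74 in the first and -0.65 in the second KO library. For the 63 of these genes with a mean of at least 5 FPKM in WT, the median ratio of KO to WT FPKM was 0.580, against 1.002 for all tested genes at that level. The 148 tested genes of the long arm before the precursor had a relative median of -0.033 (-0.11 to 0.044).

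**Figure D4:**
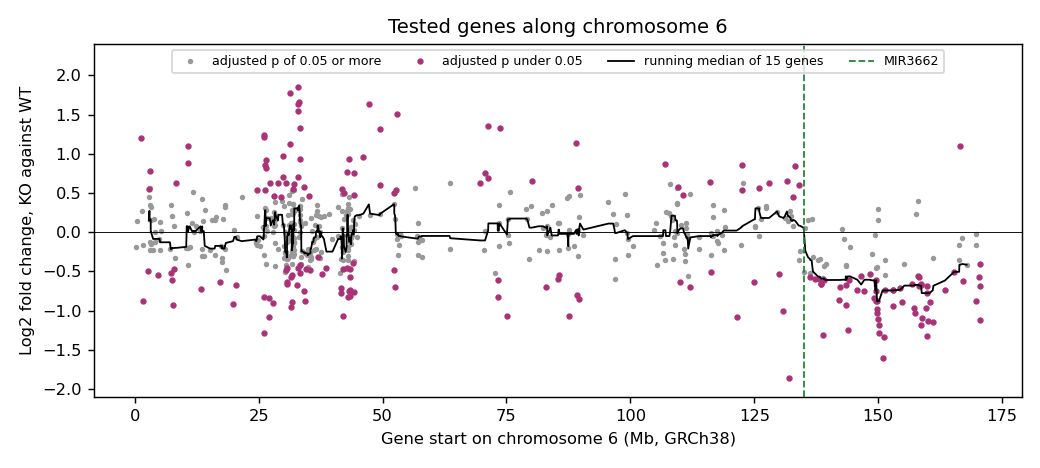
Log2 fold change of KO against WT (y axis) by gene start on chromosome 6 (x axis, Mb, GRCh38) for tested genes, with those past an adjusted p of 0.05 in purple, the running median of 15 genes as a line and the position of MIR3662 dashed. Beyond MIR3662 the median over 94 genes is -0.62.

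The last comparison asked whether genes with sites for the microRNA in their 3′ UTR were higher in KO. The match to nucleotides 2 to 8 of the mature microRNA is TCATTTT, found in 3622 of the tested genes with a 3′ UTR and missing from 7211. Genes with a match had a median log2 fold change higher by 0.029 within bins of 3′ UTR length, which was place 24 of the 42 7-mers of the same base composition (median 0.030 and maximum 0.056 of the other 7-mers). The difference was thus no larger than for other 7-mers of the same bases. Some of these, such as CATTTTT, hold part of the site and could share an effect of it. The longest 3′ UTR of HBP1, 1098 nucleotides on chromosome 7 from 107201432 to 107202529, had 0 matches to nucleotides 2 to 8. It had 1 match to nucleotides 2 to 7, CATTTT, followed by an A (chromosome 7 from 107201630 to 107201635, position 199 of the 3′ UTR).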

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

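The alternatives with a GC correction, a crossed block, gene models left out or the end of 6q left out were chosen after seeing the data. Without a filter on low values, 19833 genes were tested and 525 changed, 290 higher and 235 lower, with 422 of the original calls kept. HBP1 then kept its log2 fold change of 1.08 but had an adjusted p of 0.0772, and HIF1A, MYC, BMP4, CST4, S100A4, CTSD, KISS1, ADAMTS6, TAGLN and MPP4 no longer passed (adjusted p 0.0508 to 0.116). More genes were tested in that setting, and a further cause was not tested. With a fold threshold 546 genes changed, 415 higher and 131 lower, by construction. Leaving out each library in turn, which assumes that the lone library of a group varies like the other group, gave 1402 to 1902 changed genes, 845 to 1183 higher and 509 to 824 lower, from fewer samples. Over the same settings HBP1 ranged from 0.82 to 1.33, and its adjusted p over all 15 alternatives ranged from 0.00173 to 0.0772. After the GC correction 4034 genes changed, with 2169 lower, and the cause was not tested. Log2 fold changes correlated with GC content at -0.166 (Spearman, across genes). Of the 37 fixed gene lists, 0 passed camera with an estimated correlation, which has little power with 2 residual degrees of freedom, and 0 passed fry. The settings of camera counted next all kept the preset correlation of 0.01. Over 15 other settings of camera, the antigen presentation list passed in 15, hypoxia in 15, interferon response in 14, NF-κB in 14, the ATF4 list in 14, cholesterol synthesis in 13 and Wnt targets in 12, and the endothelial markers in 10 of 14. No call turned its direction in any setting run. The labels give replicate numbers but no shared culture, so the main fit had no replicate block. Deviations of same-numbered libraries correlated at -0.177 across genes. Other differences between libraries could also give such a correlation, so it cannot decide whether the numbers pair the libraries. With the replicate block 2864 genes changed, 2709 of them among the original calls, and no list or named gene lost its call. The crossed pairing as a block gave 4170. The place of the site among the 42 7-mers was 10 for 8mer sites and 26 for a match in any annotated transcript. Without single libraries the differences ran from -0.00035 to 0.067. In settings chosen after seeing the data, the place was 5 for sites to nucleotides 2 to 7 followed by an A and 17 after the GC correction. The 7-mers compared with the sites followed by an A were not all of the same base composition. Depth is not given, so it cannot be said how many reads stand behind genes with low FPKM.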

Other observations

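The gene lists described first, all 3 tests on the end of chromosome 6q and the search for other shifted regions were chosen after the results were seen, and the tests on HBP1 and on antigen presentation were fixed before their results were seen. Lysosomal genes were higher in KO, with 26 of 46 tested members up and none down and a median log2 fold change of 0.55 (camera adjusted p 1.75e-08, and adjusted p = 0.303 with an estimated correlation). The cholesterol carrier NPC2 rose from 112 ± 8.03 to 333 ± 33.0 FPKM, and PSAP, precursor of the saposins, from 192 ± 12.3 to 457 ± 108 FPKM. Targets of NRF2, the regulator of the antioxidant response, were higher as well, with 15 of 25 up and none down (median 0.62, camera adjusted p 1.30e-06, and adjusted p = 0.373 with an estimated correlation). The ferritin genes FTH1 and FTL rose by 1.75 and 1.84, SQSTM1 by 1.98 and NQO1 by 0.78, though ferritin genes share reads with processed copies. The other 10 members did not pass, among them GCLC (-0.018), GCLM (-0.045), SRXN1 (0.070) and TXNRD1 (0.49), so the rise did not extend to all targets. Of 23 targets of TGF-β and SMAD signalling 13 fell and 3 rose (median -0.93, camera adjusted p 6.58e-07, and adjusted p = 0.303 with an estimated correlation, unadjusted 0.0455). ID1 fell by 1.42, ID3 by 1.84 and ADAM19 by 1.70. Genes among the largest changes had prompted the lists. Leaving them out took only CTSD from the lysosomal list, so that list has no separate retest. The NRF2 list was left with 21 members (camera adjusted p 0.000204, and 0.401 with an estimated correlation), and the TGF-β list with 16, of which 6 fell and 3 rose (median -0.36, 0.0165, and 0.303 with an estimated correlation). Other members had been seen too, so these retests are not independent of the choice. With fry, which does not compare a list with other genes, the lysosomal, NRF2 and TGF-β lists passed (adjusted p 0.0292, 0.0316 and 0.0183), the latter pair also without those genes (0.0406 and 0.0183). The lists added later were adjusted only over themselves and their shortened forms, whereas the fixed lists were adjusted over 37. The unadjusted fry p of the lysosomal list, 0.0146, was close to 0.016 for the fixed hypoxia list, whose fry adjusted p was 0.149. The fry results of added and fixed lists are thus not comparable. A further list, SRF and actin targets, had 4 rises and 6 falls in 19 members (camera adjusted p 0.0394, and adjusted p = 0.441 with an estimated correlation), a fry adjusted p of 0.0550, and a camera adjusted p of 0.485 without the prompting genes. After scaling by the median of ratios it had 2 rises and 7 falls and did not pass (camera adjusted p 0.0640).

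HBP1 rose by 1.08 in KO. Copy gain around the gene is argued against by the 17 other tested genes within 2 Mb, whose median log2 fold change was -0.0122 (95% interval -0.11 to 0.37). Release from a microRNA that binds 3′ UTRs through nucleotides 2 to 8 is argued against by the lack of such a match in the longest 3′ UTR of HBP1. Over all genes, the matching site ranked in place 24 of 42 7-mers, and 8mer sites alone in place 10. Some of the other 7-mers hold part of the site. As HBP1 lacks the site, these ranks describe other genes and cannot decide on its own release. A weaker site to nucleotides 2 to 7 followed by an A, which HBP1 has, may still contribute. Such sites ranked in place 5 of 42, a test added later. Its 7-mers were not all of the same base composition, and its sites included those that also match nucleotide 8. That rank therefore cannot speak for the weaker site alone. An indirect effect of the genotype and a difference between the cell populations that predates the knockout stay open and untested.

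The antigen presentation genes rose with a median of 1.32. Copy gain of the HLA region is argued against by a median of -0.0482 (95% interval -0.16 to 0.084) over 88 other tested genes between 29 and 34 Mb of chromosome 6. Library scaling is argued against by a list median of 1.24 after scaling by the median of ratios, with 13 members up and 1 down. The camera adjusted p after scaling, 9.16e-07, cannot decide this, because camera compares a list with other genes and scaling moves most genes alike. CD68 (1.35) and ITGB2 (0.93), the only tested members of the leukocyte list, rose as well, but both were expressed in WT (34.6 and 4.84 FPKM), and leukocytes in the KO cultures are argued against by PTPRC, whose highest KO value was 0 FPKM, and by the other 7 listed markers, all below 1 FPKM. Reads shared between HLA genes do not reach B2M (1.37) or PSMB10 (1.79). A regulated rise of the pathway in KO cells was not tested here and stays open, as does a difference between the cell populations that predates the knockout.

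Genes from near MIR3662 to the end of chromosome 6q were lower in both KO libraries. A trend with GC content and transcript length is argued against by a relative median of -0.728 after correction for both. Chance in the order of genes is argued against by the lowest corrected window of 30 genes on 6q, at -0.927, against -0.43 for the lowest window of 200 random orders. The best single step along 6q lay at 136231024, the start of MTFR2, 1252 kb beyond MIR3662, with a bootstrap interval from 133952170 to 137867188 that holds MIR3662, and at 136822564 without the first WT library. A candidate explanation is loss of DNA from near the microRNA to the end of the arm in the KO cells, which no copy number data were used here to test, and a loss that predates the knockout, or regional regulation, stays open.

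After the same correction, runs of genes also shifted in 7 other regions, 1 lower and 6 higher in KO. Such a run joins windows of 30 genes with a median above 0.39 or below -0.37, limits that 5% of 200 random orders pass with their highest or lowest window, so the median over a joined run can lie inside them. On chromosome 9 from 116687302 to 137086817, the median over 177 genes was -0.39, with 69 lower and 11 higher in KO. Its lowest window, at -0.61, also lay below the lowest window of the 200 random orders, at -0.43. The block on 6q was therefore not the only one beyond them. On chromosome 4 from 7965310 to 55373096 it was 0.37 over 78 genes, on chromosome 8 from 143833594 to 144529132 it was 0.41 over 30 genes, and on chromosome 10 from 123008979 to 133421307 it was 0.41 over 32 genes. On chromosome 14 from 23058564 to 34462774 it was 0.39 over 50 genes, and on chromosome X it was 0.41 over 60 genes from 77899438 to 119471319 and 0.34 over 36 genes from 130339888 to 150898816. The set of runs depends on the correction. Those on chromosomes 8 and 10 were found only with it. Without it, with medians taken relative to all genes, the limits were 0.39 and -0.40, and further runs lay on chromosome 2 from 135906677 to 169701708 (0.37) and from 172427354 to 189877629 (0.36), on chromosome 4 from 70992538 to 83335153 (0.37) and on chromosome 10 from 103367967 to 118755249 (0.32).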
